A study of Mus musculus with 60 samples.

How the data were processed

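The values are log2 signals that the submitters' processing notes attribute to RMA, which corrects background, normalizes between arrays and summarizes probes before deposit; its version is not given in the sources used here. They were used as deposited, without further normalization. The notes do not say whether all 60 arrays were normalized together. No value was missing, and the values ran from 2.542 to 14.812. The pair of arrays with the most values in common shared 0.408% of them, so no array was a copy of another.

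The table holds 45101 probe sets, of which 64 are controls and were left out. The platform annotation, dated August 2016, gives 34945 probe sets a single gene symbol, 932 several symbols and 9160 none. Probe sets with several symbols or none were not assigned to a gene. Of the single-symbol probe sets, 34741 matched a mouse RefSeq gene table through their gene identifier, which was used for names only, and 0 symbols changed. This left 18193 genes. Where a gene had more than 1 probe set, as 9010 did, the probe set with the highest mean over all arrays stood for it, and other probe sets are mentioned where they were called in the opposite direction.

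All 60 arrays entered a single limma fit (lmFit) with a mean for each of the 20 groups, which leaves 40 residual degrees of freedom. Differences were contrasts of group means, averaged over ages or over positions. They were tested on both sides with eBayes and a trend of spread on level, and p-values were adjusted with the Benjamini-Hochberg method over all genes. A gene counts as called at an adjusted p under 0.05. Jaws were compared at single ages only within a labelled batch, and ages only within a batch. The SD beside a level is the spread of arrays within groups, pooled over the groups averaged.

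The genes named follow a rule set before the data were examined. For each comparison the 10 called genes with the largest difference in each direction were named, provided that the mean reached log2 6 in the higher group, that the symbol was not a predicted model, that the sign of the difference was the same at every age or at both positions, whether or not it was called there, and that the gene was not sex-linked. For the interactions 5 per direction were taken. Within a described list up to 4 called members with the smallest p could be named, or those of highest level where few were called. Genes outside this rule are said to be chosen after their values were seen. The table has no detection calls. Genes with a group, or several groups, at or under 4.78, the highest 25th percentile of any array, were, for position in the mandible, Hpse2, Dsc3, Dlg2, Zic1, Sim2, Myl2, Crh, Tnnt2, Epyc and Smpx, in the maxilla Rerg, Dkk4, Elf5, Slc17a6, Scn9a and Onecut2, for the jaws at E11.5 Gpr50, Aspn, Dsc3, Ppp1r17, Pou4f1, Foxl2os, Zic1 and Slc17a6, at E12.5 Ibsp, Panx3, Matn1, C1qtnf3, Scin, Neurod1, Foxl2os, Ppp1r17 and Scn9a, for the mandible at E11.5 Ogn, Aspn, Cbln4, Myh3, Mymx, Agtr2, Myl2 and Lin28a, for the maxilla at E13.5 Ibsp, Matn1, Panx3, C1qtnf3, Dpt and Hemgn, at E14.5 Bpifa1, Serpinb11, Deup1 and Ppp1r17, and for the mandible at E14.5 Mmp13, Dsc1, Sdr16c6, Nhlh2, Rab3c and Calb1, and these differences are lower bounds at best. The same holds for the log2 differences of Cryba1 and Six6 between the jaws at E11.5. To see which named genes and list members were called within single ages or pieces, a step added after the results were seen, contrasts of 3 arrays against 3 were taken from the same fit.

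There were 31 gene lists, 18 of pathways and processes and 13 of cell types, fixed before the data were examined from general knowledge of jaw development. Each was tested with camera in limma at a preset correlation of 0.01 and also with an estimated correlation, adjusted by Benjamini-Hochberg over the lists of a comparison. Members were counted as higher, lower or not called over all genes and again after adjustment over the list alone.

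Alternatives planned beforehand were a repeated quantile normalization, centring of each array on its median, leaving out dim genes (highest group mean under log2 8.45), the mean of a gene's probe sets, all probe sets as units, only the arrays compared, eBayes without trend or robust, array quality weights, the replicate number as a fixed or random block, the mean of distal and proximal arrays, leaving out each replicate number or each array in turn, a 2-fold limit, and comparisons across batches. Further alternatives chosen after seeing the data left out the 2 mandible E11.5 arrays with a raised distribution (distal replicate 3 and proximal replicate 1), left out E11.5 from the position comparisons, or took each group mean as a single sample. The last fitted a mean for each jaw and age and a single position effect per jaw to the group means. Its spread is how far the position difference varies with age within a jaw. It asks whether a difference exceeds that variation rather than the spread between arrays, and variation between ages or jaws does not enter it.

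The fit was tested on simulated data with the same design, in which 200 of 18193 genes were changed. Apart from these changes each gene had the same mean and SD in all groups, with independent normal noise. Batches, unequal spread and shared pools were not simulated, so the recovery checks the computation and not the real calls. At a log2 size of 0.5 it recovered 100% of them in the mandible position comparison and 79.1% in the interaction of jaw with age, and at a size of 2 it recovered 100% in each comparison simulated. Between 6 and 16 unchanged genes were called.

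R 4.3.3 with limma 3.58.1 was used for all tests, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for tables and figures.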

Results

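Expression was profiled on Affymetrix Mouse Genome arrays in the upper jaw (maxilla) and lower jaw (mandible) of C57Bl/6 mouse embryos, from 3 micrograms of total RNA per array. Each jaw was sampled as a distal and a proximal piece at embryonic days E10.5, E11.5, E12.5, E13.5 and E14.5. This gives 20 groups of 3 arrays, 60 arrays in all. The series belongs to the FaceBase consortium, and its stated purpose is a genome-wide picture of gene activity while the mandible and maxilla form. Values are log2 signals, so a difference of 1 is a doubling. The median signal of an array lay between 6.06, in distal maxilla E10.5 replicate 1, and 6.31, in distal mandible E11.5 replicate 3. The number of arrays limits the precision of every value. No background was measured, so a gene whose mean in a group of 3 arrays is at or under 4.78, the highest 25th percentile of any array, is not shown to be present there. A fold or log2 difference that includes such a group, also within an average, is a lower bound at best (a fold given alone is written as at least). An interaction that includes such a group is of uncertain size, and where a mean over ages or pieces is that low its size is not measured.

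The titles place the arrays in 4 batches. Batch 1 holds the mandible at E13.5 and E14.5, batch 2 the mandible at E12.5 and the maxilla from E12.5 to E14.5, batch 3 both jaws at E11.5 and the mandible at E10.5, and batch 4 the maxilla at E10.5. Both positions of a jaw and age share a batch, so each simple difference below is formed within batches. The interactions and the changes of a difference set differences from different batches against each other. A batch shift that adds to all values cancels there, but a batch difference in the scale of the signals would not. Jaws at E10.5, E13.5 and E14.5 lie in different batches, where batch and jaw cannot be told apart. Labels do not say whether the 3 arrays of a group come from separate embryos. The p-values therefore measure the spread between arrays within groups, pooled over all groups, which can be technical. The comparisons, tests and gene lists were chosen before the data were examined.

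Distal and proximal mandible were compared to see how expression varies along the length of the lower jaw. Alx1, a homeobox gene of facial mesenchyme, was 21.5-fold higher distally, with a log2 difference of 4.43 (SE 0.116) and levels of 10.93 ± 0.19 against 6.50 ± 0.36 (mean ± within-group SD, 15 arrays each). Hand2, a transcription factor of the distal arch, was 5.12-fold higher (12.70 ± 0.10 against 10.35 ± 0.19), and Shh, the Sonic hedgehog ligand, was 3.96-fold higher. Higher in the proximal piece were Zic1, at least 9.15-fold, Sim2, at least 8.88-fold, and Oc90, a matrix protein of the inner ear's otoconia, with -3.13 (SE 0.106). The cardiac myosin light chain Myl2 was at least 7.79-fold lower distally on average over the ages. Insyn2b, Dio2, Hpse2, Dsc3, Dlg2, Dsc2 and Dkk1 were 2.82-fold to 3.79-fold higher distally, and Crh, Tnnt2, Myl4, Epyc, Smpx and Tnnc1 were 6.00-fold to 7.60-fold lower. The difference of all 20 genes had the same sign at each of the 5 ages, as the naming rule asks (limma, adjusted p of the average 2.06e-16 or less), but only 13 were called at every age. Zic1 and Oc90 were not called at E10.5 and E11.5, Myl2 at E11.5 and E12.5, Hpse2, Crh and Epyc at E10.5, or Dkk1 at E14.5.

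All 7 measured members of the distal arch patterning list were higher distally (7 adjusted over the list alone, median 1.25, camera adjusted p = 8.61e-12), Bmp4 by 1.35 and Msx2 by 1.25. All 9 members of the proximal arch patterning list were lower (9 adjusted over the list alone, median -0.99, camera adjusted p = 3.95e-13), among them Barx1 at -1.86 and Nr2f1 at -2.24. The 10 Hox genes, which mark the arches behind the jaw, were all lower distally (10 adjusted over the list alone, camera adjusted p = 6.31e-08), Hoxa2 by the largest amount at -3.02. Of 14 maxillary and palate regulators, 2 were higher and 11 lower, the same over the list alone (camera adjusted p = 4.83e-08), with Meox2 at -1.82. All 5 hedgehog targets were higher (5 adjusted over the list alone, median 0.98, camera adjusted p = 8.98e-12), including Ptch1 at 0.89 and Foxf1 at 1.48. So were all 8 Bmp targets (8 adjusted over the list alone, median 0.57, camera adjusted p = 7.67e-09), such as Smad6 at 0.69, and all 7 Wnt targets (7 adjusted over the list alone, median 0.57, camera adjusted p = 5.34e-07), such as Rnf43 at 0.68. Tooth development genes were 11 higher and 3 lower of 19, also over the list alone (camera adjusted p = 0.00153), with Lhx8 and Sostdc1 up by 0.96 and 1.01.

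Tissue markers also differed between the pieces. All 20 skeletal muscle genes were lower distally (20 adjusted over the list alone, median -1.65, camera adjusted p = 6.68e-28), such as Tnnc1 at -2.58 and Myog at -1.36. Tnnc1 varied with age, at -3.77, -1.19, -4.64, -2.17 and -1.14 from E10.5 to E14.5. The cardiac Myl2 was at -7.19 at E10.5 and -0.07 at E12.5, and whether the 2 genes share a source at E10.5 was not tested. Cartilage genes were lower for 18 of 20 (18 adjusted over the list alone, median -0.85, camera adjusted p = 1.02e-14), with Epyc at -2.84, Matn1 at -2.34 and Sox9 at -1.02. Surface epithelium genes were higher for 14 of 16, none lower (14 higher and 1 lower adjusted over the list alone, median 0.66, camera adjusted p = 1.98e-14), among them Trp63 at 0.94. Markers of Schwann cells and neural crest glia were all lower, 7 of 7 (7 over the list alone, camera adjusted p = 1.05e-06), with Fabp7 at -2.15. Neuron markers were lower for 11 of 15 and higher for 1 (12 and 1 adjusted over the list alone, camera adjusted p = 1.3e-09), Prph at -2.23 and Nefl at -2.14, but adjusted p = 0.0689 with an estimated correlation. Macrophage markers were lower for 12 of 13 (12 over the list alone, camera adjusted p = 2.98e-07, adjusted p = 0.0689 with an estimated correlation), and pigment cell genes for 5 of 6 (6 over the list alone, camera adjusted p = 0.00019, adjusted p = 0.0568 with an estimated correlation), with Lyz2 at -0.60 and Dct at -1.37. These averages over ages do not hold at each age, since the medians at E10.5 were 0.10 for Hox genes, 0.03 for glia, 0.14 for neurons and 0.34 for macrophages. Sex-linked transcripts did not pass the test as a list (median -0.04, camera adjusted p = 0.946), with Xist at 0.05 (SE 0.345). This does not show an equal sex mix, since the list joins Xist with Y-linked genes, which sex moves in opposite directions. The SE of Xist is also pooled over batches with unlike within-group SD, such as 2.27 in batch 1 and 0.06 in batch 2.

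limma called 6596 of 18193 genes in the mandible, 3335 higher and 3261 lower distally, and 270 of these differed at least 2-fold, 61 higher and 209 lower. Centring each array on its median changed the split to 4712 higher and 2644 lower. Taking each group mean as a single sample, an alternative chosen after seeing the data, left 548 genes called and ended the calls of Zic1 (adjusted p = 0.0575), Oc90 (adjusted p = 0.0959) and Myl2 (adjusted p = 0.0991).

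**Figure D1:**
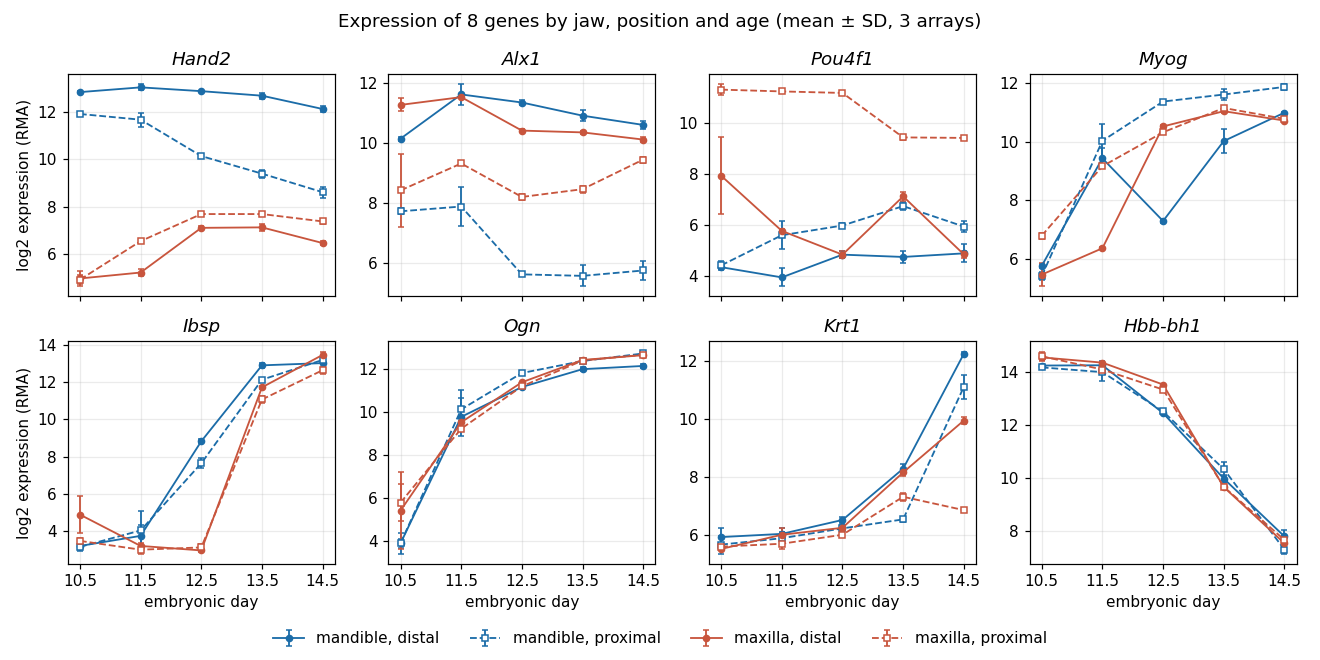
Expression of 8 genes in log2 units (vertical axis) by embryonic day (horizontal axis), with points at the mean of 3 arrays, bars of 1 SD, colour for the jaw, and filled or open symbols for distal or proximal pieces. Hand2 lies near 12.83 in the distal mandible at E10.5 and at 4.99 in the distal maxilla, and Ibsp reaches 13.01 in the distal mandible at E14.5.

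The same comparison in the maxilla asks how the upper jaw varies along its length. Its leading genes were neuronal and lower in the distal piece. Prph, the neurofilament-like protein peripherin of peripheral neurons, was 23.0-fold lower, with a log2 difference of -4.52 (SE 0.103) and levels of 6.82 ± 0.41 against 11.34 ± 0.17 (15 arrays each). Sncg was 22.5-fold lower and Pou4f1, a transcription factor of sensory neurons, 21.2-fold lower. Slc17a6, Ppp1r1c, Snap25, Prrxl1, Scn9a, Stmn3 and Onecut2 were 15.2-fold to 20.1-fold lower. Higher distally were Alx1, by 1.97 (SE 0.116), Msx1, a homeobox gene of facial mesenchyme and teeth, by 1.86 (SE 0.101), and Pax3, by 1.60 (SE 0.065). Rerg, Pmaip1, Dkk1, Dkk4, Aldh1a3, Krt14 and Elf5 were 2.61-fold to 3.56-fold higher. These 20 genes also kept their sign at all 5 ages (limma, adjusted p of the average 3.91e-17 or less), and 18 were called at each, all but Aldh1a3, not called at E13.5 and E14.5, and Elf5, not at E10.5.

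All 15 neuron markers were lower in the distal maxilla (15 adjusted over the list alone, median -3.36, camera adjusted p = 1.02e-24), with Isl1 at -3.38 and Gap43 at -1.45. All 7 markers of Schwann cells and neural crest glia were lower with them (7 over the list alone, median -1.02, camera adjusted p = 5.59e-09), Sox10 at -1.45 and Fabp7 at -3.15. Surface epithelium markers moved the other way, with 16 of 16 higher distally (16 over the list alone, median 0.90, camera adjusted p = 2.11e-14), such as Esrp1 at 1.05 and Epcam at 0.88. All 20 cell cycle genes were higher (20 over the list alone, median 0.29, camera adjusted p = 3.77e-12), Aurka by 0.36 and Top2a by 0.29. All 7 Wnt targets were higher (7 over the list alone, median 0.71, camera adjusted p = 6.8e-06), Axin2 by 0.71 and Lef1 by 1.25. Tooth development genes were higher for 15 of 19 and lower for none (16 and 0 adjusted over the list alone, camera adjusted p = 1.4e-06), Lhx8 by 1.26 and Lhx6 by 1.16. Bone genes were higher for 10 of 13 (10 over the list alone, median 0.58, camera adjusted p = 0.00468), with Sp7 at 0.70, but adjusted p = 0.286 with an estimated correlation. Muscle genes were lower for 17 of 20 (18 over the list alone, median -0.60, camera adjusted p = 5.78e-05, adjusted p = 0.365 with an estimated correlation), but at E12.5 and E13.5 none was called.

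In the maxilla 9213 genes were called by limma, 5748 higher and 3465 lower distally, and 483 differed at least 2-fold, 51 higher and 432 lower. After centring of the arrays 9196 were higher and 2620 lower. With group means as single samples 3731 genes were called, and Dkk4 was not (adjusted p = 0.0608).

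Whether position acts differently in the jaws was tested as the mandible's distal-minus-proximal difference less that of the maxilla. Isl1, a LIM homeobox gene of sensory neurons and the distal arch, was higher distally by 0.54 (SE 0.069) in the mandible and lower by a log2 difference of -3.38 (SE 0.069) in the maxilla, which differ by 3.92 (SE 0.098, 30 arrays per jaw). Snap25 was -0.88 in the mandible against -4.19 in the maxilla. Aldh1a3, an enzyme of retinoic acid synthesis, had opposite signs, -1.04 in the mandible and 1.53 in the maxilla, a difference of -2.57 (SE 0.155). Prrxl1 and Nhlh2 differed by 3.51 and 3.17, and Smpx and Tnnt2 by -2.33 and -2.30. Pou4f1, C1qtnf3 and Hoxa2 were also named, but each had a mean at or under 4.78 among the 4 that enter, so the size of their interaction is not measured. Single groups were that low for Snap25, Nhlh2, Aldh1a3, Smpx and Tnnt2. The adjusted p of these 10 genes was 7.5e-13 or less (limma).

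Of the fixed lists, the 15 neuron markers all differed upward (15 over the list alone, median 2.14, camera adjusted p = 2.32e-21), and so did 6 of 7 glia markers (6 over the list alone, median 0.60, camera adjusted p = 5.93e-05), among them Gfra3 at 0.76. Proximal arch patterning genes differed downward for 9 of 9 (9 over the list alone, median -1.27, camera adjusted p = 4.86e-09), where Barx1 was -1.86 in the mandible and 0.35 in the maxilla. Maxillary and palate regulators differed downward for 12 of 14 and upward for 1 (13 and 1 adjusted over the list alone, median -0.81, camera adjusted p = 8.52e-09), with Irx5 at -1.26 and Foxl2 at -1.22. All 20 cell cycle genes differed downward (20 over the list alone, median -0.22, camera adjusted p = 4.01e-10), including Cdk1 at -0.31. All 9 genes of the retinoic acid pathway differed downward (9 over the list alone, median -0.46, camera adjusted p = 3.19e-05), with Dhrs3 at -0.46. Fgf targets differed downward for 6 of 8 (6 over the list alone, median -0.61, camera adjusted p = 8.54e-05), as in Il17rd, at -0.51 in the mandible and 0.38 in the maxilla. Hedgehog targets differed upward for 4 of 5 (4 over the list alone, median 0.61, camera adjusted p = 0.000384), with Ptch1 at 0.89 against 0.28.

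The interaction was called for 7267 genes, 2932 upward and 4335 downward, and after centring for 2480 upward and 5853 downward. When group means stood as single samples 680 genes were called, without Nhlh2 (adjusted p = 0.135), C1qtnf3 (adjusted p = 0.219), Tnnt2 (adjusted p = 0.176) or Hoxa2 (adjusted p = 0.287).

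Within single ages, with 3 arrays against 3, the position difference varied with age. The genes shown for this were chosen after their values were seen. Hand2 was higher in the distal mandible by 0.92 (SE 0.116) at E10.5 and by 3.49 (SE 0.116) at E14.5, a growth of 2.58 (SE 0.163, limma adjusted p = 1.49e-17). In the maxilla Alx1 went from 2.85 to 0.67 (SE 0.260 each), a decline of -2.18 (SE 0.368, adjusted p = 9.63e-06). Prph shifted by -3.30 in the maxilla between these ages (SE 0.326, adjusted p = 2.91e-11), but not steadily, at -2.57, -5.24, -6.88, -2.06 and -5.87 from E10.5 to E14.5. The neuron list had a median of -4.87 at E12.5, -1.70 at E13.5 and -3.76 at E14.5. The signals of Myl2, at or under 4.78 in the distal mandible, differed by -7.19 (SE 0.231) at E10.5, by -0.10 at E11.5 and -0.07 at E12.5, where the proximal piece was under 4.78 too, and by -5.57 (SE 0.231) at E14.5.

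From E10.5 to E14.5 in order, position called 3474, 1625, 5951, 4609 and 4871 genes in the mandible and 3666, 6317, 7097, 2858 and 6123 in the maxilla. The change between E10.5 and E14.5 itself was called for 4624 genes in the mandible and 2707 in the maxilla (limma). Leaving out the arrays numbered 2 lowered the mandible counts at E10.5, E13.5 and E14.5 to 1817, 2796 and 2967, the maxilla counts at E10.5 and E13.5 to 2086 and 1593, and the counts of change to 2708 and 1688. The mandible at E11.5 gave 300 genes and the maxilla at E10.5 1414 when only the compared arrays were fitted.

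Mandible against maxilla at E11.5, in batch 3, asks what sets the jaws apart at that age. Hand2 was 87.7-fold higher in the mandible, with a log2 difference of 6.46 (SE 0.082) and levels of 12.35 ± 0.23 against 5.90 ± 0.10 (6 arrays each). Pitx1, a homeobox gene of the lower jaw and hindlimb, was 8.69-fold higher (SE of the log2 difference 0.081), and Dlx6, a homeobox gene of lower-jaw identity, 5.28-fold (SE 0.137). Higher in the maxilla were Ppp1r17, at least 20.5-fold, Neurod1, a transcription factor of differentiating neurons, at -4.15 (SE 0.259), and Fabp7, a lipid-binding protein of glia, at -3.86 (SE 0.189). Gpr50, Aspn, Rtl3, Cited1, Tbx4, Actc1 and Dsc3 were 5.07-fold to 13.3-fold higher in the mandible, although another probe set for Dsc3 was called lower. Stmn3, Pou4f1, Foxl2os, Stmn2, Ppp1r1c, Zic1 and Slc17a6 were 9.39-fold to 13.3-fold lower. The 20 genes had the same direction at both positions and were called at each (limma, adjusted p of the average 1.64e-13 or less).

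Mandibular identity genes, a list around the endothelin and Dlx pathway, were higher in the mandible for 13 of 14 (13 over the list alone, median 1.5, camera adjusted p = 3.03e-21), with Plagl1 at 1.09. Maxillary and palate regulators were lower for 8 of 14 and higher for 1 (10 and 2 adjusted over the list alone, median -0.42, camera adjusted p = 7.51e-07), with Foxl2 at -2.51 and Pou3f3 at -0.97, and their medians were -0.86 in the distal and 0.01 in the proximal pieces. Muscle genes were higher for 18 of 20 (19 over the list alone, median 1.83, camera adjusted p = 3.64e-16), Myog by 1.97 and Myod1 by 1.76. All 15 neuron markers were lower in the mandible (15 over the list alone, median -2.88, camera adjusted p = 5.34e-33), along with 6 of 7 glia markers (6 over the list alone, median -0.93, camera adjusted p = 1.6e-10), as in Isl1 at -2.27 and Sox10 at -1.15. The neuron markers Neurod1 and Stmn2, named above, were lower in both pieces but by more in the proximal ones. The mandible was also lower for 3 of 5 forebrain genes (3 over the list alone, median -1.08, camera adjusted p = 0.000577), Lhx2 by a difference of -1.68 and Six3 by -1.08, and for 3 of 8 eye and lens genes (3 over the list alone, median -0.19, camera adjusted p = 0.00425), Cryba1 at -1.85 and Six6 at -1.72. Retinoic acid pathway genes were lower for 3 of 9 and higher for 1 (the same over the list alone, median -0.17, camera adjusted p = 0.00159), with Aldh1a3 at -2.50 and medians of -0.33 distally and 0.06 proximally. Endothelial markers were higher for 7 of 11 (8 over the list alone, median 0.22, camera adjusted p = 0.000541, adjusted p = 0.161 with an estimated correlation), and pericyte and smooth muscle markers for 4 of 7 (5 over the list alone, median 0.32, camera adjusted p = 0.00741, adjusted p = 0.0538 with an estimated correlation), with Erg at 0.91 and Acta2 at 1.77.

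At E11.5 limma called 6092 genes, 3862 higher and 2230 lower in the mandible. The median within-group SD of the mandible groups at this age was 0.144 and 0.120, against 0.0614 to 0.113 in the other 18 groups. The split became 3463 higher and 2444 lower after centring, 3270 and 2818 after a repeated quantile normalization, and 2714 and 2868 without the 2 mandible arrays whose whole distribution lay above the rest. Fitting group means as single samples left 82 genes and ended the calls of 11 of the 20 genes, with adjusted p from 0.0565 for Pitx1 to 0.273 for Zic1.

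At E12.5 the jaws were compared within batch 2. Ibsp, bone sialoprotein, was at least 36.2-fold higher in the mandible, with a log2 difference of 5.18 (SE 0.206) and levels of 8.23 ± 0.21 against 3.05 ± 0.13 (6 arrays each). Hand2 was 17.0-fold higher (SE of the log2 difference 0.082), and Matn1, the cartilage matrix protein matrilin 1, was at least 9.13-fold higher (SE 0.229). Foxl2, a forkhead factor, was 8.16-fold lower in the mandible, at 7.61 ± 0.16 against 10.64 ± 0.05, and Hoxd1 was 10.8-fold lower. Panx3, C1qtnf3, Scin, Sgms2, Aspn, Rtl3 and Hapln1 were 4.88-fold to 11.2-fold higher, and Neurod1, Foxl2os, Nefl, Ppp1r17, Nefm, Prph, Scn9a and Ppp1r1c were 6.09-fold to 9.18-fold lower. Each of the 20 genes had the same sign in distal and proximal pieces (limma, adjusted p of the average 7.57e-11 or less), but C1qtnf3, Ppp1r17, Scn9a and Ppp1r1c were not called in the distal piece.

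Surface epithelium genes were higher in the mandible for 16 of 16 (16 over the list alone, median 1.03, camera adjusted p = 4.05e-17), Epcam by 1.37 and Cldn7 by 1.47. Mandibular identity genes were higher for 11 of 14 and lower for 1 (12 and 1 adjusted over the list alone, median 0.71, camera adjusted p = 4.62e-08), Pitx1 by 1.96 and Dlx4 by 1.24. Maxillary and palate regulators were lower for 11 of 14 (11 over the list alone, median -0.56, camera adjusted p = 2.87e-08), and proximal arch patterning genes for 8 of 9 (8 over the list alone, median -0.73, camera adjusted p = 4.5e-06), with Nr2f1 at -1.89 in both lists, but the medians were -1.20 and -1.29 in the distal and 0.16 and 0.01 in the proximal pieces. All 5 hedgehog targets were higher (5 over the list alone, median 0.67, camera adjusted p = 0.000177), with Hhip at 1.16. All 15 neuron markers were lower (15 over the list alone, median -2.32, camera adjusted p = 1.83e-17). Cartilage genes were higher for 15 of 20 and lower for 1 (16 and 1 adjusted over the list alone, median 1.22, camera adjusted p = 4.62e-08), Acan by 2.18, but adjusted p = 0.207 with an estimated correlation. Bone genes were higher for 7 of 13 (7 over the list alone, median 0.42, camera adjusted p = 5.16e-05, adjusted p = 0.147 with an estimated correlation), Sp7 by 1.41. Muscle genes were lower for 16 of 20 (17 over the list alone, median -1.07, camera adjusted p = 8.44e-07, adjusted p = 0.229 with an estimated correlation), an average of opposite differences, with 19 lower in the distal pieces (median -3.31) and 17 higher in the proximal pieces (median 1.07).

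limma called 7508 genes at E12.5, 4363 higher and 3145 lower in the mandible, and after centring 3761 were higher and 3707 lower. The change of the jaw difference from E11.5 to E12.5 was called for 5784 genes, of which Hand2 (-2.37, SE 0.116, adjusted p = 2.64e-21) and Actc1 (-3.64, SE 0.240, adjusted p = 8.11e-17), an actin of striated muscle, were picked after their values were seen. Group means as single samples gave 991 genes at E12.5 and ended the calls of 9 of the 20 genes, with adjusted p from 0.0676 for Nefl to 0.217 for C1qtnf3.

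In the mandible E11.5 was compared with E10.5, also within batch 3, for the changes over a day of growth. Ogn, the matrix proteoglycan osteoglycin, rose at least 66.7-fold, by 6.06 (SE 0.287), from 3.88 ± 0.38 to 9.94 ± 0.90 (6 arrays each). Aspn, the related asporin, rose at least 24.2-fold (SE of the log2 difference 0.256), and Myog, the muscle transcription factor myogenin, 17.7-fold (SE 0.113). Igdcc3 fell by 3.60 (SE 0.123) and Lin28a, an RNA-binding protein of early embryonic cells, fell at least 5.53-fold. Averaged over the pieces the cardiac gene Myl2 fell at least 13.7-fold and Myl7 fell by 2.92. Proximal levels went from 11.73 ± 0.07 to 4.42 for Myl2 and from 11.21 ± 0.14 to 5.73 for Myl7, and in the distal piece Myl2 was not called. Cbln4, Nfix, Myh3, Mymx, Hey2, Agtr2 and Gdf10 rose 11.2-fold to 18.9-fold, and Sall4, Dusp9, Prtg, Trim71, Arid3b and Gbx2 fell 3.30-fold to 5.80-fold (limma, adjusted p of the 20 averages 2.81e-12 or less, the other 19 genes called with the same sign at both positions).

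The stage-timing list of Lin28, Hmga and related RNA-binding proteins fell for 5 of 6 (5 over the list alone, median -0.67, camera adjusted p = 3.71e-06), with Igf2bp1 at -0.83. Mandibular identity genes fell for 5 of 14 and rose for 1, also over the list alone (median -0.17, camera adjusted p = 0.00918), Cited1 and Dlx3 each at -0.78, and centring the arrays ended that call (adjusted p = 0.065). Fibroblast matrix genes rose for 13 of 15 and fell for 1, also over the list alone (median 1.99, camera adjusted p = 4.18e-09), Postn by 2.11, but adjusted p = 0.157 with an estimated correlation. All 6 tendon genes rose (6 over the list alone, median 1.16, camera adjusted p = 9.38e-05, adjusted p = 0.13 with an estimated correlation), such as Mkx at 1.67. Muscle genes rose for 16 of 20 and fell for 1 (17 and 1 adjusted over the list alone, median 1.38, camera adjusted p = 2.27e-07, adjusted p = 0.264 with an estimated correlation), Myod1 by 2.25. Cell cycle genes fell for 14 of 20 (15 over the list alone, median -0.20, camera adjusted p = 1.83e-07, adjusted p = 0.0739 with an estimated correlation), Plk1 by a difference of -0.69. Macrophage markers rose for 12 of 13 (12 over the list alone, median 0.35, camera adjusted p = 0.00297, adjusted p = 0.352 with an estimated correlation), such as C1qa at 0.75.

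This comparison called 8054 genes, 5044 higher and 3010 lower at E11.5, including the mandible E11.5 arrays of wide spread (median SD 0.144 and 0.120). Centring the arrays moved the median of all genes by -0.171 and the split to 2694 higher and 8084 lower, and quantile normalization gave 3919 and 5057. On group means as single samples 2237 genes were called, without Myl2 (adjusted p = 0.108), Myl7 (adjusted p = 0.079) or Gbx2 (adjusted p = 0.102).

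Between E12.5 and E13.5 the maxilla, in batch 2, gained bone and cartilage transcripts. Ibsp rose at least 322-fold, by 8.33 (SE 0.206), from 3.05 ± 0.13 to 11.38 ± 0.15 (6 arrays each). Matn1 rose at least 55.3-fold (SE of the log2 difference 0.229) and Ifitm5, an osteoblast membrane protein, 10.2-fold (SE 0.126). Hbb-bh1, an embryonic beta globin, fell by 3.78 (SE 0.072), and Hba-x, the embryonic zeta globin, fell by 1.65 (SE 0.069). Panx3, C1qtnf3, Sgms2, Dpt, Cytl1, Prap1 and Hapln1 rose 10.1-fold to 26.3-fold. Hemgn, Slc4a1, Kel, Trib3, Pantr1, Pax1, Ppbp and Sst fell 2.49-fold to 3.73-fold (limma, adjusted p of the 20 averages 3.06e-07 or less, all called with the same sign at both positions).

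Cartilage genes rose for 18 of 20 (18 over the list alone, median 1.86, camera adjusted p = 1.43e-17), Col9a1 by 1.85 and Epyc by 2.05. Bone genes rose for 10 of 13 (10 over the list alone, median 1.61, camera adjusted p = 5.27e-10), Omd by 2.56 and Phex by 2.52. All 16 surface epithelium genes rose (16 over the list alone, median 0.83, camera adjusted p = 1.04e-12), Krt8 by 1.40, as did 6 of 8 genes of stratifying epithelium (7 over the list alone, median 0.51, camera adjusted p = 0.000157), Krt1 by 1.61. All 5 hedgehog targets rose (5 over the list alone, median 0.68, camera adjusted p = 4.05e-06), Hhip by 1.90 and Gli1 by 0.60. Erythroid genes fell for 7 of 8 (8 over the list alone, median -0.79, camera adjusted p = 8.19e-07), and stage-timing genes for 4 of 6 (4 over the list alone, median -0.55, camera adjusted p = 0.000108), Hmga2 at -0.55. All 15 fibroblast matrix genes rose (15 over the list alone, median 1.12, camera adjusted p = 1.99e-11, adjusted p = 0.0708 with an estimated correlation), Col14a1 by 2.24.

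limma called 8027 genes, 4455 higher and 3572 lower at E13.5. After centring, which moved the median of all genes by -0.136, 2733 were higher and 8907 lower, and after quantile normalization 3788 and 5326. From group means as single samples came 1316 genes, without C1qtnf3 (adjusted p = 0.0651), Pantr1 (adjusted p = 0.135) or Sst (adjusted p = 0.341).

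The maxilla at E14.5 was compared with E13.5, also within batch 2. Bpifa1, a secreted protein of airway epithelium, rose at least 26.6-fold, by 4.73 (SE 0.098), from 4.69 ± 0.21 to 9.42 ± 0.10 (6 arrays each). Dmp1, a matrix protein of osteocytes and dentine, rose 16.5-fold (SE of the log2 difference 0.179), and Dynlrb2, a dynein light chain of cilia, 5.59-fold (SE 0.165). Prap1 fell by 3.58 (SE 0.306) and Hbb-bh1 fell by 2.07 (SE 0.072). Serpinb11, Cyp2f2, Dmkn, Cbr2, Deup1, Aldh1a1 and Cma1 rose 3.23-fold to 6.34-fold. Ppp1r17, Guca2b, Hba-x, Crh, Irs4, Cxcl14, Ina and Afp fell 2.29-fold to 6.16-fold. Aldh1a1 had the highest adjusted p of these, 0.00441 (limma), and it was not called without the arrays numbered 1 (adjusted p = 0.0738). Within single pieces Aldh1a1, Crh and Ina were not called proximally and Irs4 not distally.

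Bone genes rose for 12 of 13 (12 over the list alone, median 1.23, camera adjusted p = 2.05e-19), Mmp13 by at least 2.36 and Phex by 1.56. Stratifying epithelium genes rose for 7 of 8 (7 over the list alone, median 0.93, camera adjusted p = 7.49e-12), Krt10 by 0.84 and Krt4 by 1.13. Hedgehog targets rose for 4 of 5 (5 over the list alone, median 0.35, camera adjusted p = 2.94e-05), Hhip by 0.86, and stage-timing genes fell for 4 of 6 (4 over the list alone, median -0.36, camera adjusted p = 1.18e-05), Hmga2 at -0.71. Neuron markers fell for 12 of 15 (12 over the list alone, median -0.82, camera adjusted p = 1.77e-10), Nefm at -1.68, but adjusted p = 0.0893 with an estimated correlation. In the distal pieces 13 of 15 were lower (median -1.78), and in the proximal pieces 0 were called (median 0.17). The difference between the pieces in this change was not itself tested. Distally 14 of 15 had risen from E12.5 to E13.5 (median 2.03). Macrophage markers rose for 12 of 13 (12 over the list alone, median 0.43, camera adjusted p = 1.06e-10, adjusted p = 0.062 with an estimated correlation), Csf1r by 0.54.

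Here 4208 genes were called by limma, 1869 higher and 2339 lower at E14.5 (1951 and 2434 after centring), or 2355 without the arrays numbered 2 and 6849 with array quality weights. Group means as single samples left 6 genes, and 16 of the 20 genes above lost their call, with adjusted p from 0.0568 for Guca2b to 0.819 for Ina.

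The mandible over the same interval, in batch 1, gained epidermal transcripts. Krt1, a keratin of differentiating epidermis, rose 19.2-fold, by 4.26 (SE 0.105), from 7.41 ± 0.13 to 11.67 ± 0.30 (6 arrays each). Dsc1, a desmosomal cadherin of upper epidermis, rose at least 35.6-fold (SE of the log2 difference 0.119), and Mmp13, a collagenase of bone and cartilage, at least 74.0-fold (SE 0.158). Hbb-bh1 fell by 2.62 (SE 0.072) and Nnat, neuronatin, fell by 1.15 (SE 0.064). Dmkn, Sdr16c6, Krt77, Krtdap, Dmp1, Krt4 and Cma1 rose 12.4-fold to 37.8-fold, and Hba-x, Nhlh2, Cbln4, Rab3c, Calb1, Hoxd1, Nap1l2 and Csrnp3 fell 2.12-fold to 3.76-fold. Both positions showed the same sign for the 20 genes (limma, adjusted p of the average 1.47e-05 or less), and all but Nhlh2, in the distal piece, were called at each.

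All 8 genes of stratifying epithelium rose (8 over the list alone, median 3.14, camera adjusted p = 1.63e-27), Krt10 by 3.30. Surface epithelium genes rose for 13 of 16 and fell for 2, also over the list alone (median 0.51, camera adjusted p = 4.55e-10), Perp by 1.28. Bone genes rose for 10 of 13 (10 over the list alone, median 0.60, camera adjusted p = 1.15e-08), Omd by 1.24. All 13 macrophage markers rose (13 over the list alone, median 0.58, camera adjusted p = 2.28e-13), Lyz2 by 0.99 and C1qa by 0.63. Muscle genes rose for 18 of 20 (19 over the list alone, median 1.10, camera adjusted p = 3.36e-15, adjusted p = 0.0574 with an estimated correlation), Ckm by 2.80. Immediate early stress genes rose for 3 of 10 and fell for 1, also over the list alone (median 0.09, camera adjusted p = 0.0319, adjusted p = 0.175 with an estimated correlation), Fos by 1.12 and Egr1 by 0.69.

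This interval called 5563 genes in the mandible, 2426 higher and 3137 lower at E14.5, and 2215 higher and 4013 lower after centring. Group means as single samples gave 246 genes, and 8 of the 20 genes lost their call, with adjusted p from 0.056 for Nnat to 0.672 for Nhlh2.

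The jaws were then compared in their change from E13.5 to E14.5. Krt1 rose by 4.26 in the mandible and by 0.67 in the maxilla, a difference of 3.59 (SE 0.149, 12 arrays per jaw). Krt77 and Prap1 differed by 3.06 and 2.91, and Pifo, Wdfy1 and Foxa1 by -1.92, -1.53 and -1.46. Dsc1, Mmp13, Bpifa1 and Dynlrb2 were also named, but each had a mean at or under 4.78 among the 4 that enter, so the size of their interaction is not measured, and Pifo was that low in 1 group (limma, adjusted p of the 10 genes 0.000102 or less). Stratifying epithelium genes differed in favour of the mandible for 7 of 8 (7 over the list alone, median 2.21, camera adjusted p = 1.27e-35), Krt10 by 2.47. Muscle genes differed the same way for 14 of 20 (19 over the list alone, median 0.97, camera adjusted p = 1.49e-20), Ckm by 2.08, but adjusted p = 0.0528 with an estimated correlation.

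The interaction was called for 1124 genes, 655 upward and 469 downward, or 613 and 725 after centring, and for 649 genes without the arrays numbered 3, 737 without dim genes and 2359 with array quality weights. Group means as single samples gave 15 genes, and 7 of the 10 lost their call, among them Bpifa1 (adjusted p = 0.205), Mmp13 (adjusted p = 0.455) and Krt1 (adjusted p = 0.48).

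**Figure D2:**
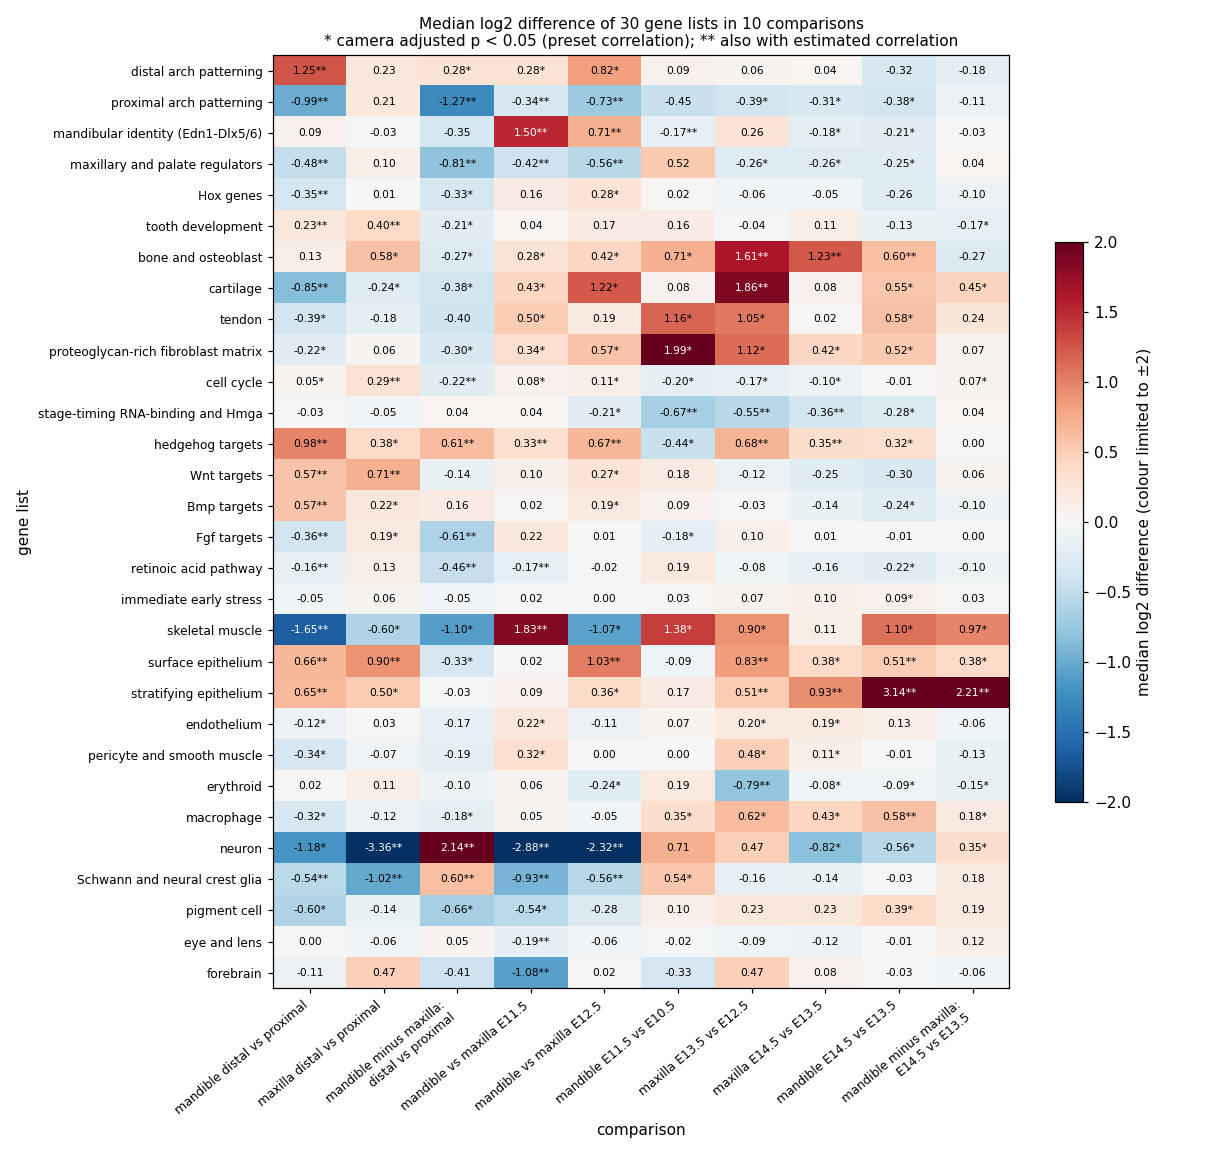
Median log2 difference (colour) of 30 gene lists (vertical axis) in the 10 comparisons (horizontal axis), where the colour scale ends at 2 in either direction and asterisks mark lists that pass camera with a preset correlation or also with an estimated one. The neuron list lies at -3.36 for distal against proximal maxilla and the stratifying epithelium list at 3.14 for the mandible from E13.5 to E14.5.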

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

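The tests of explanations and the other splits of the arrays described here were chosen after the results had been seen. Results are listed because a difference between groups was itself tested and called by limma at an adjusted p under 0.05.

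The position difference was not the same in both jaws for 7267 genes. Lists that differed, given as the median of mandible minus maxilla, were neuron (2.14), hedgehog targets (0.61), Schwann and neural crest glia (0.60), proximal arch patterning (-1.27), maxillary and palate regulators (-0.81), Fgf targets (-0.61), the retinoic acid pathway (-0.46) and cell cycle (-0.22). Of the 20 genes named for the mandible 19 differed, of the 20 named for the maxilla 18, and all 10 named for the interaction. The last count was fixed by the naming rule, which takes only called genes. Naming by a large difference in a single jaw also favours a difference between the jaws, so these counts are not independent evidence.

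The signs and sizes below are those of log2 signals. Where 1 of the 4 means that enter was at or under 4.78, the highest 25th percentile of any array, the size is not measured. This holds for Sim2, Myl2, Crh, Pou4f1, Slc17a6, Scn9a, Onecut2, C1qtnf3 and Hoxa2 in the position difference, for Gpr50, Aspn, Pou4f1, Zic1, Slc17a6, Ibsp, Panx3, Matn1, C1qtnf3 and Scin in the jaw difference, and for Bpifa1, Dynlrb2, Deup1, Ppp1r17, Mmp13, Dsc1 and Sdr16c6 in the change from E13.5 to E14.5. The size is uncertain where only single groups were that low, as for Dio2, Hpse2, Dsc3, Dlg2, Zic1, Tnnt2, Myl4, Epyc, Smpx, Rerg, Dkk4, Aldh1a3, Elf5, Snap25 and Nhlh2 in the position difference, Ppp1r17, Neurod1, Foxl2os and Hoxd1 in the jaw difference, and Cyp2f2, Rab3c and Pifo in the change from E13.5 to E14.5.

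Among genes higher in the distal mandible the jaw difference in log2 units was Hand2 3.02, Alx1 2.45, Shh 1.73, Insyn2b 1.46, Dlg2 1.34, Dio2 1.27, Hpse2 0.79, Dsc3 0.70 and Dsc2 0.42. Genes lower there gave Myl2 -2.74, Smpx -2.33, Tnnt2 -2.30, Sim2 -2.21, Myl4 -2.10, Tnnc1 -1.85, Epyc -1.75, Crh -1.62, Oc90 -1.39 and Zic1 -0.68. For genes higher in the distal maxilla the values were Aldh1a3 -2.57, Pmaip1 -1.70, Dkk4 -1.08, Rerg -0.99, Elf5 -0.98, Msx1 -0.80 and Pax3 0.65. Neuronal genes lower in the distal maxilla gave Prrxl1 3.51, Snap25 3.31, Pou4f1 3.23, Ppp1r1c 3.10, Scn9a 2.96, Onecut2 2.84, Sncg 2.70, Slc17a6 2.63, Prph 2.29 and Stmn3 1.77. The interaction also named Isl1 at 3.92, Nhlh2 at 3.17, C1qtnf3 at -2.68 and Hoxa2 at -2.24.

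The difference between mandible and maxilla changed from E11.5 to E12.5 for 5784 genes, including 19 of the 20 genes named at E11.5 and 16 of the 20 named at E12.5. Naming by a large difference at E11.5 favours a smaller difference at E12.5, and naming at E12.5 favours the reverse. The counts and directions for named genes are therefore not independent evidence of change. Genes higher in the mandible at E11.5 moved by Actc1 -3.64, Hand2 -2.37, Cited1 -2.18, Dlx6 -1.98, Gpr50 -1.62, Tbx4 -1.44, Aspn -1.33, Rtl3 -1.23 and Pitx1 -1.16. Genes lower in the mandible at E11.5 moved by Zic1 3.40, Stmn2 2.01, Ppp1r17 1.58, Fabp7 1.5, Stmn3 1.40, Pou4f1 1.13, Slc17a6 1.04, Neurod1 0.95, Foxl2os 0.78 and Ppp1r1c 0.77. Genes named at E12.5 moved by Ibsp 4.39, C1qtnf3 2.80, Matn1 2.74, Panx3 2.47, Scin 2.0, Hapln1 1.84, Sgms2 1.25, Hoxd1 -2.40 and Foxl2 -0.52. E11.5 and E12.5 lie in different batches, but each jaw difference was formed inside a batch, which removes additive batch shifts and not a batch difference in scale.

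The change from E13.5 to E14.5 differed between the jaws for 1124 genes, among them 14 of the 20 named for the maxilla, 16 of the 20 named for the mandible and all 10 named for the interaction, and the stratifying epithelium list differed by a median of 2.21. Here too the 10 named for the interaction had to be called in it. Naming by a large change in a single jaw also favours a difference between the jaws. Mandible minus maxilla was Dsc1 4.23, Mmp13 3.85, Krt1 3.59, Sdr16c6 3.24, Krt77 3.06, Prap1 2.91, Dmkn 2.72, Krtdap 2.66, Krt4 2.56, Ppp1r17 2.03, Cma1 1.95, Guca2b 1.67, Irs4 1.53 and Afp 1.04. In the other direction it was Bpifa1 -4.10, Dynlrb2 -2.92, Deup1 -2.08, Pifo -1.92, Wdfy1 -1.53, Foxa1 -1.46, Cbr2 -1.31, Cyp2f2 -1.10, Rab3c -1.03, Csrnp3 -0.95, Cbln4 -0.68, Hbb-bh1 -0.55, Nap1l2 -0.53, Nnat -0.43 and Hba-x -0.37. The position difference changed from E10.5 to E14.5 for 4624 genes in the mandible and 2707 in the maxilla. For the change from E13.5 to E14.5 the jaws lie in different batches, and the change of each jaw was formed within a batch. For E10.5 to E14.5 the ages lie in different batches in each jaw, and each position difference was formed within a batch.

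Other splits of the same arrays were fitted to see how many genes a random division of them calls. In all 10 comparisons, 1 of 100 splits, the real grouping itself, called at least as many genes as the real grouping. The highest counts of another split were 3361 for position in the mandible, 4638 for position in the maxilla, 384 for its interaction with jaw, 4516 and 5952 for the jaws at E11.5 and E12.5, 6730 for the mandible at E11.5, 4856 for the maxilla at E13.5, 1932 and 2954 for E14.5 in the maxilla and mandible, and 89 for the interaction of jaw with age. The changes of the position difference from E10.5 to E14.5 gave 1858 and 1776, and the change of the jaw difference 2109, again with 1 of 100. Splits that call many genes point to structure in the arrays, since a random split can fall partly along jaw, age or position. The splits moved single arrays, and a split that mixes arrays of different groups widens the spread within its groups, which lowers its count. If the arrays of a group share a pool, the splits cannot tell whether other embryos or dissections would repeat a difference.

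For the interactions the additive effects were first left in the split data, and then as many genes as the real grouping came from 14 of 100 splits for the interaction of jaw with age (highest other 7421) and from 13 of 100 for the maxilla's change from E10.5 to E14.5 (highest other 6846). The highest others of the remaining 3 were 530, 4451 and 5139. The additive effects were removed after this result was seen, because they enter a split contrast as if they were an interaction. Both versions are given for that reason, and the values after removal rest on a choice that favoured the real grouping.

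At single ages there are only 10 splits of 3 arrays against 3, too few for a share under 0.05, so a random division as the source of the calls is neither excluded nor shown. The limits given above for splits of single arrays hold here too. The real grouping alone reached its count, 1 of 10, at every age but the mandible at E11.5, where 2 of 10 splits did and another split called 2100 genes against 1625. The highest other counts were 3, 1, 29 and 23 in the mandible at E10.5, E12.5, E13.5 and E14.5, and 948, 1, 0, 1 and 112 in the maxilla from E10.5 to E14.5.

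Neuron markers were lower in the distal than in the proximal maxilla by a median of -3.36, and what tissue carries them is a question of dissection as much as of biology. Ganglion tissue in the proximal pieces predicts that glia move too, and the median of the glia list was -1.02, which is consistent with it. Forebrain tissue in the proximal pieces predicts forebrain genes lower distally, but their median was 0.47. A lower share of mesenchyme in the proximal pieces was taken to predict more surface epithelium there, but that list was higher distally, with a median of 0.90. This cannot decide the question, since neural tissue in the proximal pieces would lower the shares of mesenchyme and epithelium alike. The median was -2.91, -4.17, -4.87, -1.70 and -3.76 from E10.5 to E14.5, and why the distal piece at E13.5 had more neuronal signal was not tested. These tests cannot separate a ganglion that belongs to the proximal maxilla from one carried along in dissection.

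The mandible E11.5 groups spread more between arrays than other groups, with a median SD of 0.144 and 0.120 against at most 0.113. A shift of the whole intensity distribution might cause this, but after a repeated quantile normalization the SDs were still 0.119 and 0.109, against at most 0.0817 in the other groups of the batch and at most 0.113 in the other 18 groups. Measured against the batch it is not the whole cause, while against all groups the proximal mandible lies inside the range and the question stays open there. Tissue of unequal stage is consistent with the slopes of each array's deviations on the maxilla's change from E12.5 to E13.5, whose SD was 0.119 and 0.239 against 0.00764 to 0.0682 in the other 18 groups. Tissue taken from slightly older and younger embryos may lie behind part of the spread. Slopes on no other contrast were taken, so these do not single out stage. The largest slope, 0.264 (0.22 after quantile normalization), was that of proximal replicate 1, a raised array.

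In batch 2, Xist varied less between arrays of a group (SD 0.06) than between groups (SD 0.69), a ratio of 11.6. A single pool of tissue behind the 3 arrays of a group predicts a high ratio and is consistent with it. Separate pools of many embryos each predict a ratio near 1, and the median ratio of the Y-linked genes was 2.71, with which they cannot be told apart from a single pool. In batch 3, which holds the jaws at E11.5 and the mandible at E10.5, the Xist ratio was 3.77 (SD 0.19 and 0.71) and the Y-linked ratios 2.63 to 2.77, while in batch 4 the Xist ratio was 0.397. In batch 1 it was 0.576, with a within-group SD of 2.27, which is in line with arrays of a group that differ in the sex of their tissue. The fit pools each gene's spread over all 60 arrays, so no comparison is judged by the spread of its own batch alone. If the arrays of a group in batch 2 or 3 share a pool, the p-values of every comparison would rest partly on technical spread. No biological explanation was tested.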

How the results depend on the processing

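The alternatives that left out the 2 raised mandible E11.5 arrays, left out E11.5, or took group means as single samples were chosen after seeing the data; the others were planned. No result for a named gene or a list reversed under the alternatives in which it was followed. The balance of genes higher and lower did turn in several comparisons. After centring it was 2694 higher and 8084 lower for the mandible at E11.5, 2733 and 8907 for the maxilla at E13.5, and 613 and 725 for the jaw interaction at E14.5, and after quantile normalization 3919 and 5057 and then 3788 and 5326 for the first 2 of these. Without the 2 raised arrays it was 2714 and 2868 for the jaws at E11.5. Position in the mandible and single ages also turned under some alternatives, among them leaving out replicate numbers. Unless said otherwise, the cause of a change was not tested.

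Of 180 results for named genes, all but those below kept their call under every alternative in which single genes were followed and could be fitted. Aldh1a1 in the maxilla from E13.5 to E14.5 lost it without replicate 1 (limma adjusted p = 0.0738). With group means as single samples 65 lost it and 115 kept it. Leaving out single arrays, the 2-fold limit and the comparisons across batches were followed as counts of genes only. Of 310 list results, 98 lost their call with an estimated correlation, 14 lost and 7 gained it after centring, 5 lost and 7 gained it after quantile normalization, 10 lost and 6 gained it without the 2 raised arrays, 32 of 290 lost and 1 gained it without dim genes, and none changed with a fixed replicate block.

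With group means as single samples the counts in the order of the comparisons (position in mandible, maxilla and their interaction, jaws at E11.5 and E12.5, mandible E11.5, maxilla E13.5 and E14.5, mandible E14.5, and the jaw interaction) were 548, 3731, 680, 82, 991, 2237, 1316, 6, 246 and 15. This alternative has 20 samples in place of 60 and takes its spread from how far the position difference varies with age within a jaw, which lowers counts by construction.

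Testing all probe sets gave 11724, 17192, 12515, 10803, 13562, 15220, 14288, 6547 and 8610 in that order up to mandible E14.5, which counts more units by construction. By age it gave 6583, 2475, 10217, 7438 and 7849 in the mandible and 5563, 10446, 12786, 4487 and 10175 in the maxilla, and 8149, 4244 and 10514 for the changes of position difference in mandible and maxilla and of jaw difference. A limit of 2-fold, which can only lower counts, gave 270, 483, 503, 343, 503, 459, 397, 97, 242 and 167, by age 185, 196, 682, 677 and 538 in the mandible and 435, 758, 832, 315 and 806 in the maxilla, and 700, 650 and 282 for the changes.

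Array quality weights gave 6849 for the maxilla at E14.5, 2359 for the jaw interaction at E14.5, 6275 and 5433 for position in the mandible at E11.5 and the maxilla at E13.5, and 4070 for the maxilla's change of position difference. The weights ran from 0.148 to 30.2 and their estimation stopped before reaching its tolerance, so these counts are uncertain. Without dim genes the jaw interaction gave 737. Fitting only the arrays compared gave 300 for position in the mandible at E11.5 and 1414 in the maxilla at E10.5. Across batches, where batch and jaw cannot be told apart, the jaws at E10.5 differed in 11545 genes.

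Over the fits without each replicate number and without each single array in turn, the lowest and highest counts were 5000 and 6753 for position in the mandible, 7677 and 9195 in the maxilla, 5412 and 7673 for their interaction, 4601 and 6134 for the jaws at E11.5, 6110 and 7365 at E12.5, 6535 and 8107 for the mandible at E11.5, 6207 and 8061 for the maxilla at E13.5, 2355 and 3995 at E14.5, 3742 and 5264 for the mandible at E14.5, and 649 and 1135 for the jaw interaction. The lowest came from leaving out a replicate number each time, and the highest without a replicate number were 5743, 8422, 7002, 4950, 6806, 7360, 7690, 3107, 4461 and 763 in the same order. By age the lowest and highest over both kinds of fit were 1817 and 3199, 1254 and 1987, 4094 and 5608, 2796 and 4155, and 2967 and 4353 in the mandible, and 2086 and 3505, 4525 and 5643, 5413 and 6752, 1593 and 2363, and 4262 and 5672 in the maxilla. The changes of position difference gave 2708 and 4340 in the mandible and 1688 and 2750 in the maxilla, and the change of jaw difference 3961 and 5955. Fewer arrays lower the power by construction. Leaving out any single array moved no count by more than 1.5 times.

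With the replicate number as a fixed replicate block the counts were 6566, 9190, 7234, 5964, 7440, 8044, 8032, 4176, 5543 and 1118. The deviations of 10 of 30 pairs of distal and proximal arrays with the same number correlated above 0.1, and as a random replicate block the consensus correlation was 0.017, so the numbers do not appear to pair samples in general. The maxilla at E10.5 is an exception, where all 3 pairs did (r = 0.34, 0.17 and 0.265) and 6 of 6 arrays matched best with their own number. Position there called 3635 genes with the fixed block of each pair against 3666 without it. Without the 2 raised arrays the counts were 6702, 9592, 7720, 5582, 7905, 7615, 8473, 4817, 6173 and 1414. Without E11.5 position gave 6834 in the mandible, 8591 in the maxilla and 6772 for the interaction. Array signals have no measured background here, so genes near the dim limit of log2 8.45 and below are measured less surely, and a difference not called there is not shown to be absent.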

Other observations

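The observations below were picked after the values were seen. Levels are means ± SD of 3 arrays.

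Embryonic globins differed in level over the ages sampled. In the distal mandible Hbb-bh1 was at 14.26 ± 0.01 at E10.5 and at 7.79 ± 0.23 at E14.5, and Hba-x was at 13.70 ± 0.03 at E10.5 and 12.09 at E13.5, while Hbb-y was at 14.55 at E10.5 and 14.05 ± 0.13 at E14.5. The early and late mandible arrays lie in different batches, which these levels do not correct for.

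Cardiac myosin light chains were high in the proximal mandible at E10.5. Myl7 was at 11.21 ± 0.14 there against 6.15 ± 0.11 in the distal piece, and at 5.73 in the proximal piece at E11.5. Myl2 was at 11.73 ± 0.07 against 4.54 ± 0.06, at 4.42 in the proximal piece at E11.5, and again at 10.06 ± 0.54 there at E14.5.

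Oc90, Cryba1 and Six6 differed in level between proximal pieces. Oc90, of the inner ear, was at 11.10 ± 0.09 in the proximal mandible at E12.5, at 6.00 ± 0.01 in the proximal maxilla at that age, and at 10.31 ± 0.03 there at E13.5. Cryba1, a lens crystallin, was at 8.24 ± 0.08 in the proximal maxilla at E12.5 and at 4.96 at E13.5. Six6, of the eye field, was at 7.23 ± 0.13, 4.24 ± 0.13 and 7.54 ± 0.10 there at E11.5, E12.5 and E13.5. What these pieces included was not analysed here.

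Levels of 4 genes at E14.5 are given in the order distal maxilla, proximal maxilla, distal mandible and proximal mandible. Bpifa1 was at 10.85 ± 0.09, 7.99 ± 0.10, 3.67 ± 0.24 and 5.10 ± 0.18. Dynlrb2 was at 8.71 ± 0.08, 6.14 ± 0.19, 4.21 ± 0.03 and 4.76 ± 0.27. Deup1 was at 7.72 ± 0.05, 5.46 ± 0.13, 4.74 ± 0.19 and 4.72 ± 0.09. Pifo was at 7.94 ± 0.11, 5.90 ± 0.06, 4.74 ± 0.13 and 5.12 ± 0.20. The jaws lie in different batches at this age.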
